A study of Mus musculus with 10 samples.

How the data were processed

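RNA was sequenced from subcutaneous tumours of 4T1, a mouse mammary carcinoma line, collected on day 14. The labels put 10 libraries in 5 groups of 2: negative control, Free-MK1775, Lipo-MK1775, and each form with the second drug, Free-MK1775+NLG919 and Lipo-MK1775+NLG. The design text names PBS for the control and NLG919 for the last group, so both groups with NLG in their name were treated as given NLG919. What the forms consist of, the doses, and whether libraries of a group come from separate mice are not given in the sources used here, so every p value measures only the spread between these samples.

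The labels name an RNeasy mini plus kit for RNA and a NEBNext Ultra kit for libraries. The processing notes name FastQC, Trim Galore, HISAT2 and StringTie on genome build GRCm39, with no versions. The deposited values are FPKM, fragments scaled to transcript length and to the mapped fragments of the library, which the authors computed per transcript with mitochondrial transcripts inside the total. Read counts were not used here and the strand setting is not stated, so reads of a gene and an antisense or overlapping partner cannot be told apart. Depth with mitochondrial reads is known only in relative terms: the smallest FPKM step of a library, scaled by transcript length, stands for 1 read.

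The table holds 161762 transcripts, of which 21051 carry no gene symbol. Of these, 14746 assembled transcripts were added to the symbol of their locus with the largest overlap and 6305 were left out. The first run of the 11 comparisons summed only transcripts with a symbol. The assembled ones were added after those results had been seen, and the first rule is kept as an alternative. Summing gave 52224 genes. Genes at an FPKM of at least 1 in at least 2 libraries were tested, which left 12765 and set aside 39459. Another symbol shares the locus of 1716 tested genes, and how the assembly split reads between such symbols is uncertain, as it is between near-identical copies such as the globin, Prl2c, mast cell protease and Rps18 pseudogene families.

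All libraries entered a single limma fit of log2(FPKM + 1) with a mean per group and a variance trend. From it came 4 comparisons against the control, 4 between treated groups, 2 averages over 4 against 4 libraries and the interaction of form and NLG919. The test was limma's moderated test, two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The 37 gene lists for pathways and cell types, the 28 genes followed in every group, the comparisons, the tests, the rule for named genes and 18 of the alternatives were set before the data were examined. Lists were tested with camera, a set test of limma that compares a list with all other genes, at a preset correlation of 0.01 and adjusted over the lists. Calls were repeated with an estimated correlation and with fry, a limma test of whether a list moves one way on balance. A list with 4 measured members was not tested, which left 36. Adjusted over the list alone means that the adjustment covered only the members of that list. List means of 4 against 4 libraries were also compared by a two-sided exact permutation test.

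The rule for named genes takes, per comparison, the 10 largest rises and 10 largest falls among genes called without overlap between the libraries of either side. Where fewer than 5 genes pass, it takes up to 4 a direction with the smallest unadjusted p, a change of at least 1 log2 unit and no overlap, given as values. It adds the 4 members with the smallest unadjusted p of each list called, and the 28 fixed genes; predicted genes, pseudogenes and genes without a symbol are counted but not named. This gave 918 pairs of gene and comparison, too many to print. A shortening to 5 genes a direction, 3 lists a direction and 2 members a list was set after the values had been seen and gave 296 pairs, of which 3 are not printed. Genes outside the rule, in 6 pairs where a comparison called 5 or fewer genes and Rn18s, are each said to have been chosen after their values were seen. Totals in the closing section cover all pairs.

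Alternatives changed a single choice at a time: the pseudocount, the filter, median-of-ratios and quantile scaling between libraries, the transcript summary, a replicate block, the variance trend, a fit of only the groups compared, and each library left out. After the data had been seen, 5 were added: FPKM rescaled to nuclear named genes, the mitochondrial share as a covariate, transcripts with a symbol only, and the fit without the 3 libraries of high mitochondrial share under either scaling. A comparison of 7 libraries of low mitochondrial share was also added, as was a comparison of the members of each list in the text with the 200 genes nearest to them in mean level, since high and low genes moved unequally. In simulated data with 100 genes changed by 1 and 100 by 2 log2 units, 4% and 46% were called for Free-MK1775 against the control. For that pair in the 7 libraries it was 66% and 94%, and for 4 against 4 libraries 30% and 90%. Unchanged genes called were 3, 5 and 5. GC content came from GENCODE transcripts of an older mouse build matched by identifier. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used. Chromosome positions are those of the deposited table.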

Results

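FPKM was measured in 10 libraries from subcutaneous 4T1 tumours on day 14. The negative control, Lipo-MK1775, Free-MK1775, Lipo-MK1775+NLG and Free-MK1775+NLG919 had 2 each. MK1775 inhibits WEE1, the kinase that holds cells at the entry to mitosis. NLG919 acts on the IDO1 pathway, which turns tryptophan into kynurenine and dampens T cells. The series concerns WEE1 and sensitivity to ferroptosis, a death driven by iron and oxidised lipids, so genes of these pathways are followed in each group. Summed FPKM ran from 328254 to 607192 per library. Relative depth ran from 1 in Lipo-MK1775 replicate 1 (nuclear read share 0.355) to 1.96 in negative control replicate 1 (0.969).

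Genes of the mitochondrial genome made up 64.1% of summed FPKM in Lipo-MK1775 replicate 1, 56% in Lipo-MK1775 replicate 2 and 47.3% in Free-MK1775+NLG919 replicate 2. In the other 7 libraries the share was 2.88% to 4.82%. The same 3 libraries had 9376, 10302 and 10588 genes at an FPKM of at least 1, against 11979 to 12191 in the others. Rn18s, the 18S ribosomal RNA gene, chosen after its values were seen, stood at 3654.6, 3617.8 and 3219.6 FPKM there and at 523.03 to 1737.9 in the others. Across genes, Free-MK1775+NLG919 replicate 2 correlated with the Lipo-MK1775 libraries at Pearson r = 0.943 and 0.947 and with the other library of its own group at 0.915. The other groups had r = 0.971 to 0.980 between their libraries. Genes are not independent replicates. As both Lipo-MK1775 libraries are among the 3, that treatment and a high mitochondrial share cannot be separated in any comparison with it.

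By limma, 1 gene was called between Free-MK1775 and the control, 52 for Free-MK1775+NLG919, 2 for Lipo-MK1775+NLG and 8500 for Lipo-MK1775. The unadjusted p was under 0.05 for 111, 2610, 179 and 9096 genes in that order. Libraries of both sides did not overlap for 35%, 43.9%, 53.2% and 89.6% of genes, where chance gives 33.33%. The share was 27.4% for Free-MK1775+NLG919 against Free-MK1775, 39.3% for Lipo-MK1775+NLG against Free-MK1775+NLG919, and 0.877% and 1.05% for the averages over NLG919 and over form, where chance gives 2.857%. The fit pools the variance of all groups, the unlike Free-MK1775+NLG919 pair included. Low counts, and jumps without 1 of that pair, can reflect this. In comparisons with Lipo-MK1775 the median of all genes moved (-1.08 log2 units against the control), so changes there are also given relative to it.

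**Figure D1:**
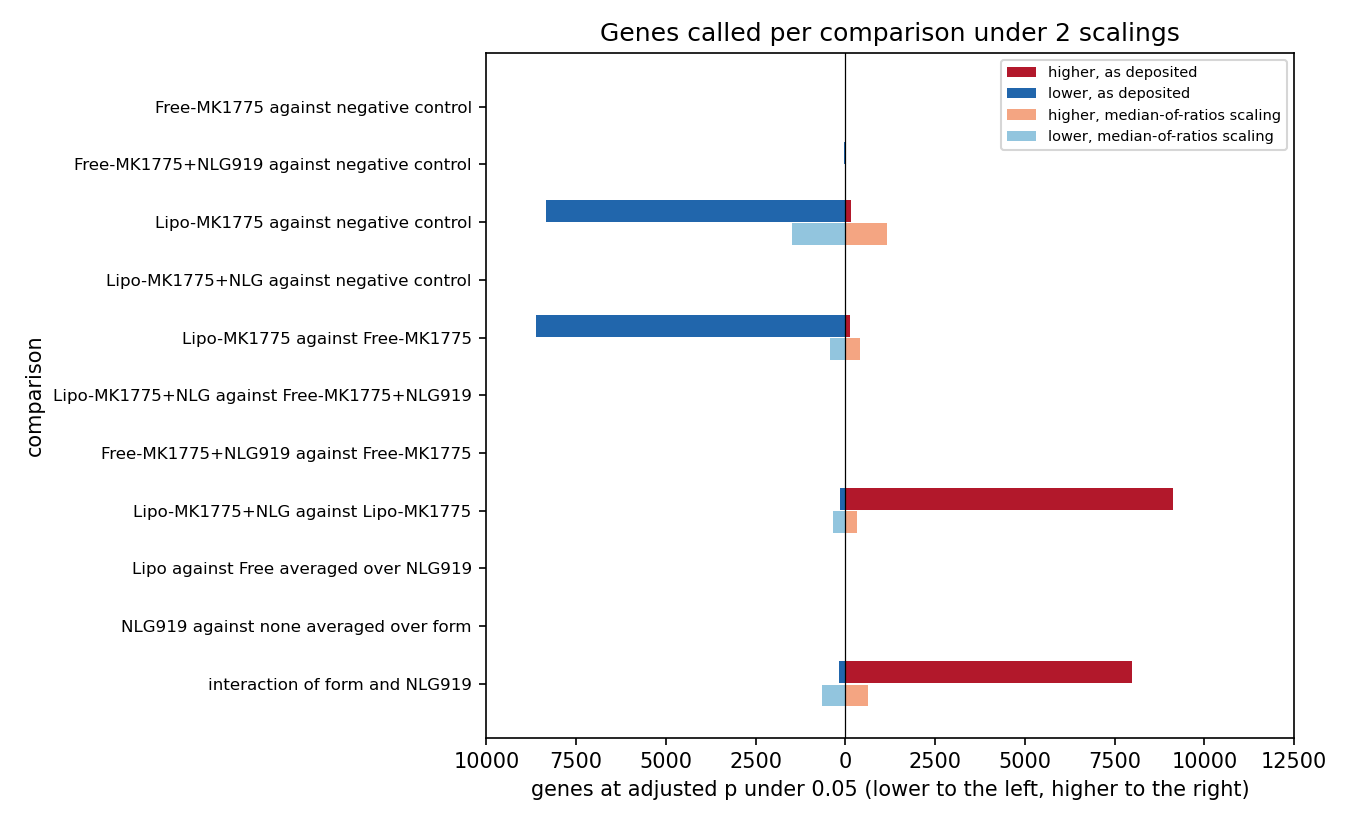
Number of genes called up and down in each comparison, with the deposited FPKM and with median-of-ratios scaling between libraries. Against the control, Lipo-MK1775 has 151 up and 8349 down with the deposited values and 1146 up and 1486 down after scaling.

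Free-MK1775 against the control asks what the free WEE1 inhibitor changed on its own. Erythroid genes stood higher: Hbb-bs, a beta globin, was at 31.2 ± 5.83 FPKM (SD, n = 2) in the control and 128 ± 8.50 in Free-MK1775. Its log2 change was 2.02 (SE 0.43, adjusted p = 0.498), and the alpha globins Hba-a1 and Hba-a2 had 2.04 and 1.90; reads of these near-identical pairs can be split between copies. Of 6 erythroid genes, 5 were higher, and adjusted over the list alone 5 rose, while over all genes limma called 0 of them (camera adjusted p = 5.72e-20; adjusted p = 0.0587 with an estimated correlation). Mast cell genes were lower in 8 of 8 members with a median of -1.10 (camera adjusted p = 1.63e-13, and 0.412 as the adjusted p with an estimated correlation); the carboxypeptidase Cpa3 had -1.58 and the tryptase Tpsab1 -1.54. Mcpt1, a mast cell protease, was at 1.29 and 1.01 FPKM in the control and listed at 0 in Free-MK1775. The cytokine Il24 had -1.94 (SE 0.38, adjusted p = 0.378), Thada -2.13, the AMPK subunit Prkaa1 -2.60 and the bone matrix gene Ibsp 1.79, none of them called. Prkaa1 shares its locus with other symbols, and its control libraries were at 320 and 79.6 FPKM.

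Ribosomal protein genes, such as Rpl3 (0.26) and Rplp2 (0.23), were higher in 22 of 24 members after Free-MK1775 (camera adjusted p = 0.0239), but by 0.00982 over genes of the same level. Macrophage genes, such as Lyz2 (0.77) and Cx3cr1 (0.53), were higher in 13 of 19 (0.0278 by camera). Genes of ATF4 and the unfolded protein response, such as Chac1 (-0.74) and Asns (-0.61), were lower in 16 of 22 (camera adjusted p = 0.0239), and skin genes, such as Dmkn (-1.38) and Trp63 (-0.51), in 12 of 12 (0.0179 by camera). For each of these 4 lists the adjusted p was 0.988 with an estimated correlation, and of all lists called, 4 up and 6 down, 0 held. Of the 24 measured genes followed in every group, limma called 0, and 0 had an unadjusted p under 0.05: Wee1 had -0.18, the lipid peroxide reductase Gpx4 0.15, the cystine carrier Slc7a11 -0.24, the lipid ligase Acsl4 0.44, the transferrin receptor Tfrc -0.55 and Ido1 0.17. The ferroptosis defence and driver lists had medians of -0.022 and -0.014 (camera adjusted p = 0.828 and 0.451).

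The gene called in Free-MK1775 against the control was Rps18-ps6 (GRCm39 chromosome 13, 97896580 to 97897140; adjusted p = 2.4e-09), a pseudogene outside the rule and chosen after its values were seen. It was at 537 and 517.9 FPKM in the control and listed at 0 in Free-MK1775, where the overlapping Rps18-ps4 was at 323.5 and 303.5 and the control at 0. Without negative control replicate 2 the count was 28, and it was 2 without negative control replicate 1 or either Lipo-MK1775+NLG library. Leaving out 1 library also ended list calls, given as list median minus the median of all genes. Ribosomal proteins went to 0.0591 without negative control replicate 1 and 0.0576 without Free-MK1775 replicate 1, and macrophages to 0.101 and 0.0188. The ATF4 list went to -0.0743 without negative control replicate 2 and -0.115 without Free-MK1775 replicate 2. Skin genes went to 1.25 without negative control replicate 1 and 0.778 without Free-MK1775 replicate 1, both reversed, to -2.66 without negative control replicate 2, and lost the call at an unchanged -0.569 without either Free-MK1775+NLG919 library. With the call kept, ribosomal proteins went to 0.224 without negative control replicate 2 and 0.245 without Free-MK1775 replicate 2, where macrophages went to 0.371 and skin to -2.04, and mast cells to -0.722 without Free-MK1775 replicate 1. For erythroid genes 3 rose adjusted over the list alone without negative control replicate 1, and for mast cell genes that count, 1 with all libraries, ran from 0 to 5.

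Free-MK1775+NLG919 against the control asks what the free inhibitor changed together with NLG919. Tfrc, which takes up iron, fell from 47.1 ± 10.2 FPKM (SD, n = 2) to 6.73 ± 3.55, a log2 change of -2.70 (SE 0.41, adjusted p = 0.0105; GRCm39 chromosome 16, 32427738 to 32451612). The glutathione-degrading ATF4 target Chac1 fell as well (-1.92, adjusted p = 0.0375), and these were the 2 of the 24 followed genes that limma called. Il24 (-2.83, adjusted p = 0.00756), Prkaa1 (-3.80), the annexin Anxa8 (-3.85) and the placental hormone gene Prl2c3 (-4.77, SE 0.39, adjusted p = 1.9e-05), of a family of near-identical copies, fell. Mast cell genes were lower in 7 of 8 members (median -2.22), and Cpa3 (-2.56) and Tpsab1 (-3.05) fell. Ramp1 (2.58), a receptor partner for neuropeptides, Tmem223 (2.39), Bend5 (1.77) and Megf6 (1.68) rose. Wee1 had -1.10 (adjusted p = 0.166), Ido1 -1.28 (0.139), Gpx4 -0.06, Slc7a11 -0.23 and Acsl4 -0.01.

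Genes of mitosis, such as Anln (-1.79) and Cenpf (-1.37), were lower in 22 of 24 members after Free-MK1775+NLG919; over all genes limma called 0, and adjusted over the list alone 18 fell. DNA damage genes, such as Topbp1 (-1.47) and Atm (-1.20), were lower in 19 of 21, with 0 called and 5 adjusted over the list alone. Mitochondrially encoded genes, such as mt-Atp6 (3.74) and mt-Nd6 (2.94), were higher in 15 of 15 with 0 called; the mitochondrial share was 47.3% in replicate 2 and 2.88% in replicate 1. Ribosomal protein genes, such as Rps18 (0.75) and Rps2 (0.73), were higher in 23 of 24 with 0 called, and erythroid genes, such as Hba-a1 (1.83), in 4 of 6. The camera adjusted p was 7.73e-05, 0.00484, 1.63e-12, 1.18e-08 and 0.00073 for these lists and 0.00026 for mast cells. With an estimated correlation the adjusted p was 0.966 or 0.987 for each. The median of all genes was -0.37, and 8 genes rose and 44 fell with the deposited values, 9 and 16 under median-of-ratios and 54 and 72 under quantile scaling.

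Leaving out Free-MK1775+NLG919 replicate 2, the library of high mitochondrial share, ended 10 of the 12 named calls in this comparison, among them Tfrc (-2.22), Il24 (-2.74) and Chac1 (-1.62), and left 4 genes called; without replicate 1 of that group 7855 were called. Without negative control replicate 1 or 2 the count was 14 and 99, and 8 and 2 named calls ended; without either Lipo-MK1775 library it was 10, and 7 ended at unchanged values, Tfrc (-2.70) and Chac1 (-1.92) included. The Prl2c3 call held with each library left out. The list medians relative to all genes without Free-MK1775+NLG919 replicate 2 were -0.129 for mitochondrially encoded, 0.189 for ribosomal and 0.845 for erythroid genes, and without replicate 1 -1.23 for mast cells, and these calls ended. The median change of mitosis genes went from -1.05 to -0.423 and that of DNA damage genes from -0.808 to -0.234 without Free-MK1775+NLG919 replicate 2, with the camera calls kept. Of mitosis genes 0 fell by limma adjusted over the list alone without that library or either control library, and 0 DNA damage genes with any library but Free-MK1775+NLG919 replicate 1 left out, where 18 fell; of mast cell genes 4 fell without replicate 2. Without replicate 1, mitochondrially encoded genes went to 4.95 relative to all genes, ribosomal proteins to 1.29 and Megf6 to 1.09, all still called.

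Lipo-MK1775 against the control asks what the Lipo form changed on its own, in the pair of libraries at 64.1% and 56% mitochondrial share. Wee1, the target of the drug, fell from 11.2 ± 0.716 FPKM (SD, n = 2) to 2.92 ± 0.414, a log2 change of -1.65 (SE 0.38, adjusted p = 0.0043), or -0.57 relative to the median of all genes (GRCm39 chromosome 7, 109721253 to 109743374). Gpx4, the reductase that blocks ferroptosis, fell from 241 ± 29.6 to 134 ± 37.8 FPKM, a log2 change of -0.86 (SE 0.32, adjusted p = 0.03) that was 0.22 relative to the median and 0.47 under median-of-ratios scaling. Slc7a11 fell (-1.20, adjusted p = 0.0206, relative -0.12), as did Acsl4 (-1.59, relative -0.51), Tfrc (-1.90, relative -0.82), the NRF2 gene Nfe2l2 (-1.67, relative -0.59) and heme oxygenase Hmox1 (-1.46, relative -0.38). Ido1 fell (-0.98, adjusted p = 0.0309, relative 0.10), and Ido2, Chac1, Ptgs2, Pkmyt1, Cdk1, Ccnb1, Cd274, Epcam and the p53 target Cdkn1a also fell. Of the 24 followed genes these 17 fell, and the ferritin Ftl1 (-0.01), Fth1 (-0.69), the coenzyme Q reductase Aifm2 (-0.62), Cd8a (-0.41), Gzmb (-0.92), Cxcl9 (-0.95) and S100a8 (-0.57) were not called. Under median-of-ratios scaling Aifm2 was 0.55 and Cdkn1a 0.26, and with the mitochondrial share as covariate Slc7a11 was 0.18, Acsl4 0.11, Ido1 0.15, Ptgs2 0.01 and Cd274 0.64.

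**Figure D2:**
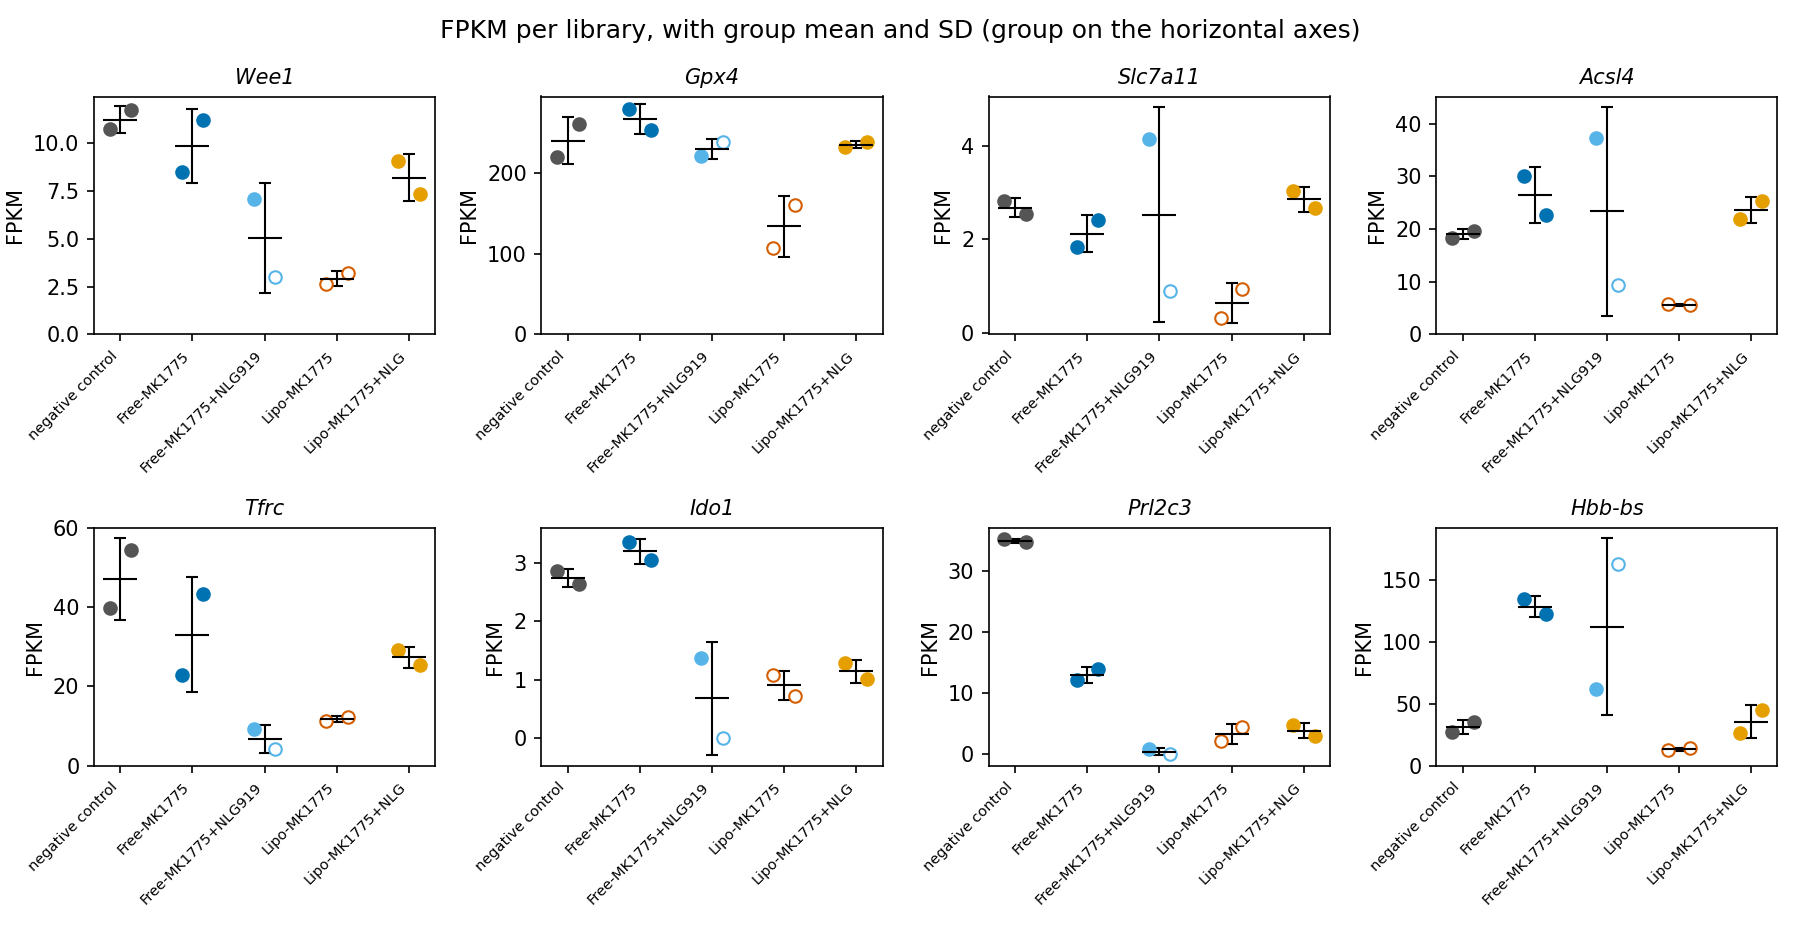
FPKM of Wee1, Gpx4, Slc7a11, Acsl4, Tfrc, Ido1, Prl2c3 and Hbb-bs in each library (points; open circles are libraries with a mitochondrial share above 25%), with group mean and SD (n = 2). Wee1 is at 11.2 in the control and 2.92 in Lipo-MK1775, and the Gpx4 change between them reverses under median-of-ratios scaling.

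After Lipo-MK1775, 8349 of 12765 genes fell (median -1.08). Of 22 ferroptosis defence genes 15 fell, also adjusted over the list alone (median -1.04, camera adjusted p = 0.75). Of 20 driver genes 16 fell, 18 adjusted over the list alone (median -1.39, 0.174 by camera). Of 19 iron genes 15 fell (median -1.20, 0.55 by camera). All 15 mitochondrially encoded genes rose (median 4.83, camera adjusted p = 1.6e-71; adjusted p = 0.054 with an estimated correlation). mt-Atp8 rose by 9.34, mt-Atp6 by 8.58, mt-Co3 by 6.85, mt-Nd6 by 5.82 and mt-Nd4l by 4.83; several symbols share these loci. mt-Nd2 rose by 8.18 with FPKM of 241.92 and 32992 in the replicates. Genes of mitosis, such as Mki67 (-2.42) and Anln (-2.61), fell in 22 of 24, with a median of -0.72 relative to all genes (camera adjusted p = 0.00551). DNA damage genes, such as Trp53bp1 (-1.78) and Blm (-1.74), fell in 21 of 21 (0.0204 by camera) and ATF4 and unfolded protein genes, such as Herpud1 (-2.24) and Atf3 (-2.11), in 22 of 22 (0.0259). MHC class II and dendritic cell genes, such as Cd209a (0.80) and Zbtb46 (-0.70), had 0 of 11 called. Their median of -0.03 was 1.05 above all genes (6.62e-07 by camera, upward). Ribosomal proteins, such as Rps18 (0.59) and Rps4x (-0.57), had 0 of 24 called and a median of 0.06, 1.14 above all genes (8.19e-16 by camera), which quantile scaling reversed to -0.016. For each of these 5 lists the adjusted p was 0.918 with an estimated correlation. The AMPK gene Prkaa1 (-4.39), the nuclear RNA Neat1 (-3.91), Derpc (-3.62), the ubiquitin ligase Ubr2 (-3.52) and the sodium pump gene Atp1b1 (-3.50) had the largest falls under the rule.

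Of the 8500 genes called in Lipo-MK1775 against the control, 1627 were also called under median-of-ratios scaling, which gave 1146 up and 1486 down where the deposited values gave 151 and 8349; quantile scaling gave 1028 and 1156. Without Lipo-MK1775 replicate 1, 3 genes were called and 32 of the 34 named calls ended, Wee1 (-1.54), Gpx4 (-0.57) and Slc7a11 (-0.92) among them; mt-Co3 and mt-Nd4l held. Without Lipo-MK1775 replicate 2 or negative control replicate 1, 7 named calls ended each, and 8 without negative control replicate 2, with Ccnb1 at -1.43, Epcam at -0.47 and Acsl4 at -1.55 in that order of libraries. The counts were 3939 and 4220 without either control library. The Gpx4 call also ended, at -0.99 and -0.74, without negative control replicate 1 and 2, and at an unchanged -0.86 without Free-MK1775 replicate 1 or either Lipo-MK1775+NLG library, and the Epcam call at -1.34 without either Free-MK1775+NLG919 library. Relative to all genes, mitosis went to -0.51 and DNA damage to -0.187 without Lipo-MK1775 replicate 2, and the ATF4 list to -0.364 without negative control replicate 2 and an unchanged -0.48 without either Free-MK1775+NLG919 library, and these calls ended. Without Lipo-MK1775 replicate 1 and 2, mt-Nd2 was 11.72 and 4.64, not called. The ATF4 list went to -0.257 without Lipo-MK1775 replicate 1, with 9 members down adjusted over the list alone, and Epcam to -2.22 without negative control replicate 2, and both calls held.

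Lipo-MK1775+NLG against the control asks what the Lipo form changed together with NLG919, and both of its libraries have a low mitochondrial share. Neutrophil genes, such as Wfdc21 (0.88) and the collagenase Mmp8 (0.77), were higher in 16 of 16 members with a median of 0.72, and S100a8 had 1.06; limma called 0 of the list over all genes and 0 adjusted over the list alone. Macrophage genes, such as Cx3cr1 (1.06) and Lyz2 (0.87), were higher in 17 of 19, and chemokine genes, such as Cxcl5 (1.10) and Csf3 (0.98), in 16 of 21. Fibroblast and matrix genes, such as Postn (-1.03) and Col5a2 (-0.95), were lower in 15 of 19, mitosis genes, such as Prc1 (-0.45) and Anln (-0.51), in 22 of 24, and skin genes, such as Lor (-1.89) and Flg (-0.81), in 10 of 12. The camera adjusted p was 3.51e-11 for neutrophils, 0.00105 for macrophages, 0.00919 for chemokines, 0.000112 for fibroblasts and 0.000515 for mitosis and for skin. With an estimated correlation the adjusted p was 0.978 for each.

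Prl2c3 (GRCm39 chromosome 13, 12805705 to 12815188) fell from 34.9 ± 0.374 FPKM (SD, n = 2) to 3.79 ± 1.24 after Lipo-MK1775+NLG, a log2 change of -2.93 (SE 0.39, adjusted p = 0.0213). Gm28037 (chromosome 16, 55786706 to 55801193; adjusted p = 0.041) was listed at 0 in the control and at 31.5 and 24.5 FPKM here; it lies outside the rule and was chosen after its values were seen. Il24 had -2.10 (adjusted p = 0.223), Prkaa1 -3.01, the transcription factor Wt1 -1.52, the basophil protease Mcpt8 1.38, Zbtb22 1.39, the oestrogen receptor Gper1 1.31 and the phosphodiesterase Pde9a 1.13, none called. Wee1 had -0.42, Ido1 -0.81, Tfrc -0.75, Gpx4 -0.02, Slc7a11 0.07 and Acsl4 0.30; limma called 0 of the 24 followed genes, with 1 at an unadjusted p under 0.05, and the ferroptosis defence and driver lists had medians of 0.051 and 0.091 (camera adjusted p = 0.547 and 1). The Prl2c3 call ended at -2.66 without Lipo-MK1775+NLG replicate 2 and -2.92 without negative control replicate 1, and at an unchanged -2.93 without either Lipo-MK1775 library; the Gm28037 call ended without any of the Free-MK1775+NLG919 or Lipo-MK1775 libraries. The count was 26 without negative control replicate 2, 1 without negative control replicate 1 or either Free-MK1775+NLG919 library and 0 without either Lipo-MK1775 library. Relative to all genes, macrophages went to 0.264, chemokines to 0.12 and skin to 0.982, a reversal, without negative control replicate 1; chemokines went to -0.0369 without Lipo-MK1775+NLG replicate 2, and skin to -0.107, with the camera direction but not the sign reversed, without replicate 1. Chemokines (0.182) and skin (-0.869) also lost the call, with the value unchanged, without either Free-MK1775+NLG919 library. With the call kept, skin went to -3.07 without negative control replicate 2 and -1.98 without Lipo-MK1775+NLG replicate 2, chemokines to 0.316 without negative control replicate 2, and chemokines to 0.461 and fibroblasts to -0.249 without Lipo-MK1775+NLG replicate 1.

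Lipo-MK1775 against Free-MK1775 asks how the Lipo form differs from the free form without NLG919. Endothelial genes, such as the cadherin Cdh5 (-2.37, relative -1.30) and Mcam (-2.47), fell in 12 of 14 members (camera adjusted p = 0.0109). Mitosis genes, such as Prc1 (-1.95) and Mki67 (-1.98), fell in 22 of 24 (0.0191 by camera), and hypoxia and glycolysis genes, such as Hk2 (-2.04) and Adm (-1.72), in 18 of 19, or 19 adjusted over the list alone (0.0281 by camera). T cell genes, such as Klrk1 (-1.35, adjusted p = 0.0413) and Lck (-0.86), were higher than other genes by camera (1.13e-06) with a negative median of -0.25, 0.82 above all genes and 0.557 above genes of the same level, since low genes have less room to fall; 1 of 16 fell, and 0 adjusted over the list alone. Ribosomal proteins, such as Rps4x (-0.75) and Rpl10 (-0.64), had 0 of 24 called by limma and a median of -0.0064, 1.06 above all genes (camera adjusted p = 5.16e-14, upward). For these 5 lists the adjusted p was 0.973 with an estimated correlation. All 15 mitochondrially encoded genes rose (median 4.85, camera adjusted p = 7.6e-86; adjusted p = 0.0353 with an estimated correlation), with mt-Nd2 at 8.54, mt-Co3 at 7.34, mt-Atp6 at 7.30, mt-Atp8 at 7.27, mt-Nd6 at 5.86 and mt-Nd4l at 4.83; the share was 64.1% and 56% against 4.82% and 3.44%. Hbb-bs (-3.21), the neutrophil granule gene Ngp (-3.41), Ubr2 (-3.52), Neat1 (-2.96) and Mir7005 (-3.09) fell. So did 13 of 24 followed and 8608 of all 12765 genes.

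In this comparison 136 genes rose and 8608 fell with a median of all genes of -1.07; median-of-ratios scaling gave 403 and 430, quantile scaling 361 and 356. Without Lipo-MK1775 replicate 1, 6 genes were called and 16 of 18 named calls ended, Hbb-bs (-3.13) and Cdh5 (-2.51) among them. Without Free-MK1775 replicate 1 and 2 the count was 3216 and 262, and 1 and 7 named calls ended, Klrk1 at -1.08 and Mki67 at -1.65 among them; without Lipo-MK1775 replicate 2, 2 ended, mt-Nd2 at 4.99 and Klrk1 at -1.38. Relative to all genes, endothelium went to -0.456 without Free-MK1775 replicate 1 and -0.528 without Lipo-MK1775 replicate 2, mitosis to -0.337 without Free-MK1775 replicate 2 and -0.325 without Lipo-MK1775 replicate 2, and hypoxia to -0.128 without Free-MK1775 replicate 2, each without its call. Endothelium (-0.575) and hypoxia (-0.299) also lost the call without either Free-MK1775+NLG919 library. With the call kept, mitosis went to -0.73 without Free-MK1775 replicate 1, T cells to 0.469 without Free-MK1775 replicate 2 and hypoxia to -0.0794 without Lipo-MK1775 replicate 1; 10 and 8 hypoxia genes fell adjusted over the list alone without the last 2 libraries.

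Lipo-MK1775+NLG against Free-MK1775+NLG919 asks how the forms differ in the presence of NLG919. Mast cell genes, such as Tpsab1 (2.02) and Cpa3 (1.69), were higher in 8 of 8 members; over all genes limma called 0, and adjusted over the list alone 6 rose (camera adjusted p = 0.0003). Cholesterol and fatty acid synthesis genes, such as Idi1 (0.99), were higher in 20 of 20 (0.00298 by camera), and mitosis genes, such as Anln (1.28) and Hmmr (1.13), in 22 of 24 (0.00423). Mitochondrially encoded genes, such as mt-Atp6 (-4.78) and mt-Atp8 (-4.53), were lower in 14 of 15, with 10 adjusted over the list alone and 0 over all genes (camera adjusted p = 2.55e-24; adjusted p = 0.39 with an estimated correlation). Ribosomal proteins, such as Rps2 (-0.55) and Rps18 (-0.49), were lower in 19 of 24 (3.64e-09 by camera), and erythroid genes, such as Hba-a2 (-1.65), in 5 of 6 (camera adjusted p = 4.24e-06; adjusted p = 0.39 with an estimated correlation). For the other 4 lists the adjusted p was 0.959 with an estimated correlation. The cathepsin Ctsk (3.36, adjusted p = 0.325), Fgfbp1 (2.34), Tfrc (1.95), Pde2a (1.68), Igf2 (-2.07), Bend5 (-1.62), Tbx2 (-1.47) and the death receptor Tnfrsf25 (-1.33) were not called, nor were any of the 24 followed genes by limma, of which 5 had an unadjusted p under 0.05.

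The gene called in Lipo-MK1775+NLG against Free-MK1775+NLG919 was again Rps18-ps6 (adjusted p = 4.06e-09), outside the rule and chosen after its values were seen, at 301.6 and 592 FPKM against 0 and 0; 1424 genes had an unadjusted p under 0.05 and the median of all genes was 0.41. Without Free-MK1775+NLG919 replicate 1, 8159 genes were called, against 2 without replicate 2 or either control library, and 5 and 4 without Lipo-MK1775+NLG replicate 1 and 2. With Free-MK1775+NLG919 replicate 2 left out, at 47.3% mitochondrial share, the medians relative to all genes were 0.109 for cholesterol, 0.169 for mitosis, -0.0811 for mitochondrially encoded, -0.0919 for ribosomal and -0.607 for erythroid genes, and those 5 calls ended. Without replicate 1 the mast cell median was 0.552 with the camera direction reversed. In the same fit cholesterol genes were at 0.757, mitochondrially encoded at -5.09, ribosomal at -1.20 and erythroid at -2.24, and mast cells were at 0.688 without Lipo-MK1775+NLG replicate 2, all called. Of mast cell genes 3 rose adjusted over the list alone without Free-MK1775+NLG919 replicate 1 and 0 by limma without replicate 2 of that group or of Lipo-MK1775+NLG. Of mitochondrially encoded genes 0 fell without Free-MK1775+NLG919 replicate 2 or either Lipo-MK1775 library and 3 without Lipo-MK1775+NLG replicate 1.

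Free-MK1775+NLG919 against Free-MK1775 asks what NLG919 added to the free form. Prl2c3 fell from 13 ± 1.32 FPKM (SD, n = 2) to 0.37 ± 0.523, a log2 change of -3.40 (SE 0.39, adjusted p = 0.00335), the 1 gene called, with 1162 at an unadjusted p under 0.05. Interferon gamma response genes, such as Ido1 (-1.45, adjusted p = 0.375) and the GTPase Gbp2 (-1.93), were lower in 23 of 23 members, with 1 down adjusted over the list alone and 0 over all genes by limma (camera adjusted p = 0.000242). WEE1 and G2/M genes, such as Ccnb1 (-1.22) and Chek1 (-0.90), were lower in 16 of 16 (0.0113 by camera), and mitosis genes, such as Top2a (-1.47) and Anln (-1.39), in 22 of 24 (0.000102). Type I interferon genes, such as Ifit3 (0.59) and Ifih1 (-0.77), were higher than other genes by camera (0.0113), with a median of -0.0092 that was 0.35 above all genes. Ribosomal proteins, such as Rps2 (0.60) and Rps18 (0.56), were higher in 20 of 24 (5.57e-09 by camera). For these 5 lists the adjusted p was 0.976 with an estimated correlation. Mitochondrially encoded genes, such as mt-Nd6 (2.98) and mt-Co3 (1.74), were higher in 15 of 15 with 0 called (camera adjusted p = 2.37e-19; adjusted p = 0.822 with an estimated correlation); the share was 2.88% and 47.3% against 4.82% and 3.44%. Mir6236 (3.40), Igf2 (2.16), Tmem223 (1.81), Bend5 (1.34), the collagenase Mmp1a (-1.89), Tfrc (-2.15) and the serotonin receptor Htr5b (-1.54) were not called, and of the 24 followed genes limma called 0, with 8 at an unadjusted p under 0.05.

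The Prl2c3 call ended at -3.31 without Free-MK1775 replicate 2 and at -3.00 without Free-MK1775+NLG919 replicate 2, which left 0 genes called. Without Free-MK1775+NLG919 replicate 1 the count was 7799, and it was 5 without either Lipo-MK1775+NLG library and 7 without either control library. Relative to all genes and without Free-MK1775+NLG919 replicate 2, the interferon gamma median was -0.0561, the WEE1 list -0.103, ribosomal proteins 0.0597 and mitochondrially encoded genes -0.268, the last reversed, and these calls ended. The type I interferon call ended at 0.353 without Free-MK1775 replicate 1 and 0.406 without Free-MK1775+NLG919 replicate 1. The mitosis median went from -0.48 to -0.283 without Free-MK1775+NLG919 replicate 2 and -0.31 without Free-MK1775 replicate 2, where the WEE1 list went to -0.197, all still called. With Free-MK1775+NLG919 replicate 1 left out, mitochondrially encoded genes were at 4.62, ribosomal at 1.18, interferon gamma at -1.34 and the WEE1 list at -0.558. In that fit 23 interferon gamma genes fell adjusted over the list alone, against 5 to 10 without a control or Lipo-MK1775+NLG library and 0 by limma without any other.

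Lipo-MK1775+NLG against Lipo-MK1775 asks what NLG919 added to the Lipo form. All 15 mitochondrially encoded genes fell (median -5.08, camera adjusted p = 3.68e-90; adjusted p = 0.0315 with an estimated correlation), as the share went from 64.1% and 56% to 2.98% and 3.49%. The changes were -10.83 for mt-Atp8, -9.61 for mt-Atp6, -8.65 for mt-Nd2, -6.84 for mt-Co3, -5.80 for mt-Nd6 and -4.83 for mt-Nd4l. The heat shock gene Hspa1a rose by 3.63 (adjusted p = 0.0047, relative 2.51), Ubr2 by 3.46, Neat1 by 3.32, and the protease inhibitors Cstdc5 and Stfa3 of neutrophils by 3.75 and 3.34. Fibroblast genes, such as Pdgfra (2.42, adjusted p = 0.006) and Pdgfrb (1.34), had 4 up and 1 down, or 3 and 1 adjusted over the list alone; the median of 0.18 was positive but -0.95 relative to all genes (camera adjusted p = 1.51e-07, downward; adjusted p = 0.905 with an estimated correlation). Ribosomal proteins, such as Rps4x (0.58) and Rpl5 (0.57), had 0 of 24 called by limma and a median of 0.076, or -1.04 relative to all genes (camera adjusted p = 5.81e-14, downward; adjusted p = 0.8 with an estimated correlation). Of the 24 followed genes 13 rose, and of the ferroptosis defence list 15 rose with a median of 1.15, where the median of all genes was 1.12.

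Between the Lipo groups, 9114 genes rose and 150 fell with the deposited values, 332 and 337 under median-of-ratios and 304 and 321 under quantile scaling. Without Lipo-MK1775 replicate 1, 7 genes were called and 11 of 13 named calls ended, Hspa1a (3.62), Pdgfra (2.48) and Neat1 (2.46) among them. Without Lipo-MK1775 replicate 2, Stfa3 (3.57) and mt-Nd2 (-5.10) lost the call. Without Lipo-MK1775+NLG replicate 2, Cstdc5 was 2.14 and Stfa3 1.14, and without replicate 1 Pdgfrb was 1.32, none called; the counts were 4052 and 1017. The Stfa3 call also ended without either Free-MK1775+NLG919 library at an unchanged 3.34. The 3 list calls described held with each library left out, and 1 fibroblast gene rose adjusted over the list alone, not 3, without any of the Lipo-MK1775 or Lipo-MK1775+NLG libraries. Stfa3 was 5.54, still called, without Lipo-MK1775+NLG replicate 1.

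Lipo against Free averaged over NLG919 sets 4 libraries against 4 to ask about the form alone. Hbb-bs (GRCm39 chromosome 7, 103475741 to 103477303) fell in the Lipo form, with a log2 change of -2.37 (SE 0.31, adjusted p = 0.00549, relative -2.03), and erythroid genes, such as Hba-a2 (-1.66), were lower in 5 of 6 members, with 1 called over all genes and 5 adjusted over the list alone (camera adjusted p = 6.32e-07; adjusted p = 0.316 with an estimated correlation). The erythroid list mean differed by -1.21 (two-sided exact permutation p = 0.0286, the smallest possible; adjusted over 37 lists 0.887). Endothelial genes, such as Cdh5 (-0.84) and Esam (-0.79), were lower in 14 of 14, with 8 adjusted over the list alone and 0 over all genes (camera adjusted p = 0.00154; adjusted p = 0.947 with an estimated correlation). Mast cell genes, such as Mcpt4 (1.16) and Cpa3 (0.73), were higher in 7 of 8 (camera adjusted p = 3.83e-12; adjusted p = 0.334 with an estimated correlation). Chemokine genes, such as Ccl8 (1.60, adjusted p = 0.204) and Cxcl3 (0.77), were higher than other genes by camera (3.22e-07; adjusted p = 0.916 with an estimated correlation) with a negative median of -0.065, 0.27 above all genes, and 1 rose adjusted over the list alone. Mitochondrially encoded genes were higher in 15 of 15 with 2 called (camera adjusted p = 4.99e-43; adjusted p = 0.167 with an estimated correlation): mt-Co3 rose by 3.05 (adjusted p = 0.0139; mitochondrial genome, 8607 to 9390) and mt-Nd4l by 2.42 (adjusted p = 9.08e-05; 9877 to 10192), and the share was high in 2 of 4 Lipo and 1 of 4 Free libraries.

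Also called were Rps18-ps6 (adjusted p = 2.01e-11), listed at 0 in all 4 Free libraries, and Rps18-ps4 (adjusted p = 0.0176; GRCm39 chromosome 13, 97887620 to 97897473), at 261.9 to 420.5 FPKM there and listed at 0 in the Lipo form except for 155.9 in Lipo-MK1775+NLG replicate 1; both lie outside the rule and were chosen after their values were seen. The median of all genes was -0.335, 1754 genes had an unadjusted p under 0.05, limma called 0 of the 24 followed genes (4 unadjusted), and 3 rose and 2 fell where both other scalings gave 3 and 0. Without Free-MK1775+NLG919 replicate 2, 8910 genes were called; without replicate 1 of that group it was 21, without either control library 13, without Lipo-MK1775+NLG replicate 2 it was 9 and without either Lipo-MK1775 library 2. The Hbb-bs call ended at -2.33 and -2.41 without Lipo-MK1775 replicate 1 and 2. mt-Co3 (2.99 and 3.12) and Rps18-ps4 also lost the call there, and without Free-MK1775+NLG919 replicate 1 (mt-Co3 2.51). The erythroid median relative to all genes without Free-MK1775+NLG919 replicate 2 was -0.716 and the endothelial -0.326, both without a call. Mitochondrially encoded genes were at 0.249 and 2.94 without Free-MK1775+NLG919 replicate 1 and 2, and mast cells at 0.561 without replicate 1 of that group, 1.33 and 0.405 without Lipo-MK1775 replicate 1 and 2 and 0.55 without Lipo-MK1775+NLG replicate 2, where chemokines were at 0.162, all called. Adjusted over the list alone, 13 endothelial genes fell without Free-MK1775+NLG919 replicate 2, 3 without Free-MK1775 replicate 2 and 0 by limma without any of Free-MK1775 replicate 1, the controls, Lipo-MK1775 or Lipo-MK1775+NLG.

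NLG919 against none averaged over form asks what blocking the IDO1 pathway changed, again 4 libraries against 4. Neutrophil genes, such as Retnlg (1.63) and the lipocalin Lcn2 (1.27), were higher in 16 of 16 members with 8 up adjusted over the list alone and 0 over all genes by limma (camera adjusted p = 0.00036; adjusted p = 0.834 with an estimated correlation); the list mean was 4.27 ± 0.415 (SD, n = 4) against 3.47 ± 0.785, two-sided exact permutation p = 0.114, adjusted over 37 lists 0.74. Interferon gamma genes, such as Ido1 (-0.64) and Nlrc5 (0.90), were lower in 17 of 23, with a median of -0.48 relative to all genes (camera adjusted p = 5.97e-13; adjusted p = 0.762 with an estimated correlation). Fibroblast genes, such as Dpt (-1.02) and Pdgfrb (0.87), were lower in 12 of 19 (camera adjusted p = 3.61e-09; adjusted p = 0.675 with an estimated correlation). Mitochondrially encoded genes were lower in 15 of 15, with 1 called and 10 adjusted over the list alone (camera adjusted p = 1.62e-58; adjusted p = 0.0852 with an estimated correlation): mt-Co3 had -2.55 (adjusted p = 0.0695) and mt-Nd4l fell (-2.41, adjusted p = 0.000189), and the share was high in 1 of 4 libraries with NLG919 and 2 of 4 without.

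The lectin gene Clec3b (GRCm39 chromosome 9, 122980011 to 122986497) fell with NLG919 (-1.26, SE 0.20, adjusted p = 0.0381, relative -1.64), as did the eosinophil ribonuclease Rnase2a (chromosome 14, 51492719 to 51493569; -2.24, SE 0.32, adjusted p = 0.0204, relative -2.62). Gm20605 (chromosome 5, 137627437 to 137641164) rose by 1.75 (adjusted p = 0.0204); it lies outside the rule and was chosen after its values were seen. The basophil protease Mcpt8 (1.47, adjusted p = 0.0695), Megf6 (1.15), Rab26os (1.07), Mapk8ip3 (1.01), the eotaxin Ccl11 (-1.27) and the chemoattractant Rarres2 (-1.98) were not called, and limma called 0 of the 24 followed genes (6 at an unadjusted p under 0.05; 2248 of all genes). The median of all genes was 0.379. Clec3b lost the call without any of the Free-MK1775 (-1.20 and -1.32), Lipo-MK1775 (-1.32 and -1.20) or Lipo-MK1775+NLG (-1.24 and -1.28) libraries. Rnase2a lost it without Free-MK1775 replicate 2 (-2.26), Free-MK1775+NLG919 replicate 1 (-2.12) or Lipo-MK1775 replicate 1 (-2.09) or 2 (-2.40), and Gm20605 without Free-MK1775 replicate 2 (1.63), Lipo-MK1775 replicate 1 (1.72) or 2 (1.77) or Lipo-MK1775+NLG replicate 1 (1.70). The count of 4 was 9489 without Free-MK1775+NLG919 replicate 2, 40 without replicate 1 of that group, 16 and 17 without negative control replicate 1 and 2, 7 without Lipo-MK1775+NLG replicate 2, 2 without Lipo-MK1775 replicate 2 and 1 without Lipo-MK1775 replicate 1 or Free-MK1775 replicate 2. Without Free-MK1775+NLG919 replicate 2 the interferon gamma median relative to all genes was -0.0784 and the neutrophil 0.22, with the camera direction of the latter reversed, and both calls ended. The interferon gamma median change was 0.521 in that fit, with 16 members up adjusted over the list alone, and -0.682 without replicate 1, with 19 down and -0.842 relative to all genes. Adjusted over the list alone, 0 neutrophil genes rose by limma without Free-MK1775 replicate 2, Free-MK1775+NLG919 replicate 1 or Lipo-MK1775 replicate 1 (0.187 relative to all genes), 3 without replicate 1 of Free-MK1775 or Lipo-MK1775+NLG, and 13 without Lipo-MK1775 replicate 2. Mitochondrially encoded genes were at -0.603 and -3.22 without Free-MK1775+NLG919 replicate 1 and 2; 3 to 5 fell adjusted over the list alone without the former, Free-MK1775 replicate 1 or either Lipo-MK1775 library. The fibroblast median change was 0.101 without Free-MK1775+NLG919 replicate 2.

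The interaction asks whether the effect of NLG919 differed between the Lipo and the free form. Mitosis genes, such as Anln (3.49, relative 2.01) and Hmmr (3.24), were positive in the interaction in 24 of 24 with 22 called (camera adjusted p = 0.00828), DNA replication genes, such as Mcm6 (3.05) and Mcm4 (3.04), in 26 of 26 with 21 called, or 22 adjusted over the list alone (0.0422 by camera), and cholesterol and fatty acid genes, such as Fasn (2.84), in 20 of 20 with 18 called, or 20 adjusted over the list alone (0.0136). Type I interferon genes, such as Ifih1 (1.95, adjusted p = 0.015) and Ifit2 (1.22), had a positive median of 0.60 that was -0.89 relative to all genes (camera adjusted p = 3.13e-06, downward), with 1 of 21 called and 0 adjusted over the list alone. For these 4 lists the adjusted p was 0.975 with an estimated correlation. All 15 mitochondrially encoded genes were negative (median -6.91, camera adjusted p = 3.13e-70; adjusted p = 0.0563 with an estimated correlation), with mt-Nd2 at -14.86, mt-Atp6 at -12.07, mt-Atp8 at -11.79, mt-Nd6 at -8.78, mt-Co3 at -8.58 and mt-Nd4l at -4.83; the share was high in Lipo-MK1775 replicate 1 and 2 (64.1% and 56%) and Free-MK1775+NLG919 replicate 2 (47.3%). Ribosomal proteins, such as Rps18 (-0.88) and Rps19 (-0.85), had 0 of 24 called by limma (camera adjusted p = 5.26e-16; adjusted p = 0.966 with an estimated correlation). Ubr2 (5.17, relative 3.69), the growth factor receptor Fgfr2 (4.97), Vcl (4.93) of cell adhesions, Neat1 (4.80) and Anxa8 (4.61) had the largest positive values under the rule, and 13 of the 24 followed genes were called, all positive.

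In the interaction 7975 genes were positive and 174 negative with the deposited values and a median of all genes of 1.48, 632 and 663 under median-of-ratios and 577 and 551 under quantile scaling. The count was 2831 without Lipo-MK1775 replicate 1, 4765 and 5414 without Lipo-MK1775+NLG replicate 1 and 2 and 5172 without Free-MK1775 replicate 2, and Ifih1 lost its call at 1.84 and 1.78 without Lipo-MK1775 replicate 1 and Free-MK1775 replicate 2. The mitosis call ended at 0.726 relative to all genes without Lipo-MK1775 replicate 2. The DNA replication call ended at 0.571 without Free-MK1775 replicate 1, 0.447 without Lipo-MK1775 replicate 2, 0.389 without Lipo-MK1775+NLG replicate 2 and an unchanged 0.454 without either control library. Still called, mt-Nd2 was -8.93, Ifih1 1.18 and cholesterol genes 0.437 relative to all genes without Free-MK1775+NLG919 replicate 2, and the type I interferon median change was -0.0082 there.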

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

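The correlation of 0.554, the Rps18-ps6 and list values beside it, the count of comparison libraries, the miss of 0.207 and the 1146 genes still called were chosen as tests only after the result was seen, as were the covariate and the scaling to nuclear genes.

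Genes of the mitochondrial genome made up 47.3% to 64.1% of summed FPKM in both Lipo-MK1775 libraries and Free-MK1775+NLG919 replicate 2, against 2.88% to 4.82% in the other 7. More mitochondria per cell were argued against, since 20 nuclear respiration genes exceeded the median nuclear gene by 0.172 log2 units in Lipo-MK1775, under the bound of 0.5. In Free-MK1775+NLG919 replicate 2 treatment with the Lipo form stays open, as values go both ways. Across 12738 nuclear genes its difference from replicate 1 followed that of Lipo-MK1775 from the control (Pearson r = 0.554). A shared fault of the libraries would give that as well. The erythroid mean was 4.171 (2.914 and 2.731 in Lipo-MK1775). The B and plasma cell mean was 1.239 (3.585 and 3.337, but also 3.581 in its own replicate 1). Rps18-ps6 was listed at 0 (412.6 and 591.3 FPKM in Lipo-MK1775). It lies within Rps18-ps4, at 420.5 here, so this 0 decides nothing. Loss of long transcripts may contribute, as the change fell with transcript length (Spearman rho = -0.499, and -0.428 within Free-MK1775+NLG919). RNA without poly(A) tails stays open. In Lipo-MK1775 9 histone genes, several of them near an FPKM of 1, were in excess by 0.876, between the bounds of 0.5 and 1. Within Free-MK1775+NLG919 the excess was 1. Other RNAs without poly(A) tails, outside that prediction and chosen after their values were seen, were Rmrp, Scarna2, Rpph1 and Rny3. Their changes were 1.79, 1.05, 0.965 and 0 in Lipo-MK1775 against the control. From replicate 1 to 2 of Free-MK1775+NLG919 they were 2.2, -0.172, 1.02 and 1. GC content stays open as well (rho = 0.154). Lipo-MK1775 treatment and library quality cannot be told apart in the Lipo-MK1775 group, which has 0 libraries of low mitochondrial share.

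The level of most genes was lower in these 3 libraries, and 8349 genes were called lower in Lipo-MK1775 than in the control. The nuclear share of reads predicted the shift of the median gene with a miss of at most 0.207 log2 units. Share and shift come from the same FPKM values, where a lower nuclear share lowers the median nuclear gene by construction. A loss of nuclear RNA would give the same agreement, so the miss does not tell dilution by mitochondrial reads from such a loss. For the genes called, 17.8% stayed called lower under median-of-ratios scaling, a share that decides neither way. Under that scaling 1146 genes were called higher and 1486 lower, which a single factor per library cannot give, so dilution alone is argued against for those. A biological effect of Lipo-MK1775 on them stays open and untested, since both of its libraries are of the kind described.

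The interaction of form and NLG919 tests a difference between effects directly, and 8149 genes passed it. The 3 libraries of high mitochondrial share all enter this contrast with the same sign, and the count was 0 with the mitochondrial share as covariate, 1295 under median-of-ratios and 1128 under quantile scaling. Among the genes named by the rule, Ubr2 had 5.17, Fgfr2 4.97, Vcl 4.93, Neat1 4.80, Anxa8 4.61, Anln 3.49, Hmmr 3.24, Mcm6 3.05, Mcm4 3.04, Fasn 2.84 and Ifih1 1.95. The mitochondrially encoded genes had -14.86 for mt-Nd2, -12.07 for mt-Atp6, -11.79 for mt-Atp8, -8.78 for mt-Nd6, -8.58 for mt-Co3 and -4.83 for mt-Nd4l.

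An assembled transcript without a gene symbol on GRCm39 chromosome 16 (57211475 to 57212045), outside the genes compared, stood at 3994.9 and 4185.7 FPKM in Lipo-MK1775 and 3697.1 in Free-MK1775+NLG919 replicate 2, against 264.5 to 957.36 in the other 7.

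In a fit of the 8 treated libraries, 2 genes were called between the Lipo and the Free form, and 7 of the 35 splits into 4 and 4 gave as many, the real one included, so chance is not excluded. The highest other split called 6592 genes and put the 3 libraries of high mitochondrial share on 1 side together with Free-MK1775 replicate 1, which points to a structure of the samples. With and without NLG919, limma called 0 genes in that fit, so all 35 splits give as many by construction, which says nothing. The highest other split was again 6592.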

How the results depend on the processing

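Genes of the same level, scaling to nuclear genes, the mitochondrial share as covariate, transcripts with a symbol only and the fits without the 3 libraries of high mitochondrial share were chosen as tests only after the result was seen. Depth and nuclear read share were lowest in Lipo-MK1775 replicate 1, which limits low genes there most. How far was not measured. Where 1 library is left out, the lone sample of its group is assumed to vary like the other groups. The fits without the 3 libraries give no value for comparisons with Lipo-MK1775, for either average or for the interaction. The replicate block tested whether the numbers pair libraries. In 10 tests of pairing the correlation was -0.34 to 0.0628, so they do not. Of the 283 calls among pairs named by the rule, 117 stayed the same under median-of-ratios, 142 lost the call and 24 reversed; quantile scaling gave 115, 154 and 14, the covariate 19, 222 and 42, and without Lipo-MK1775 replicate 1 66 stayed and 217 lost the call. With a pseudocount of 0.1, 264 stayed the same, and with the replicate block 280. Except where said, the cause was not tested.

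In counts of genes called, the pseudocount of 0.1 gave 2 for Free-MK1775 against the control, 27 for Free-MK1775+NLG919, 1 for Lipo-MK1775+NLG, 2 for Free-MK1775+NLG919 against Free-MK1775 and 1 for NLG919 against none. Without a filter these were 19, 28, 22, 2 and 1, with 4307 for Lipo-MK1775 against Free-MK1775, 3 for Lipo-MK1775+NLG against Free-MK1775+NLG919, 8 for Lipo against Free and 3564 for the interaction. The replicate block gave 2 for Free-MK1775, 89 for Free-MK1775+NLG919, 6 for the latter against Free-MK1775, 12 for Lipo against Free and 12 for NLG919. A fit of only the groups compared gave 2 for Free-MK1775, 127 for Free-MK1775+NLG919, 1 for Lipo-MK1775+NLG, 15 for Lipo-MK1775+NLG against Free-MK1775+NLG919, 25 for Free-MK1775+NLG919 against Free-MK1775, 13 for Lipo against Free and 16 for NLG919. No variance trend gave 1 for Lipo-MK1775+NLG.

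Median-of-ratios scaling gave 25 genes for Free-MK1775+NLG919 against the control, 2632 for Lipo-MK1775, 1 for Lipo-MK1775+NLG, 833 for Lipo-MK1775 against Free-MK1775, 669 for Lipo-MK1775+NLG against Lipo-MK1775, 3 for Lipo against Free and 1295 for the interaction. In Lipo-MK1775 against the control it reversed Aifm2 (0.55), Cdkn1a (0.26) and Gpx4 (0.47), by construction, since it moves each library by a factor. Quantile scaling gave 126, 2184, 1, 717, 625, 3 and 1128 in that order and 8 for NLG919, and reversed Aifm2 (0.61) and Cdkn1a (0.11). It also ended and reversed the camera direction of ribosomal proteins, whose medians relative to all genes became 0.00709 in Free-MK1775, -0.0861 in Free-MK1775+NLG919 and -0.016 in Lipo-MK1775 against the control, 0.0179 in Lipo-MK1775 against Free-MK1775, 0.0697 in Lipo-MK1775+NLG against Free-MK1775+NLG919, -0.0117 in Free-MK1775+NLG919 against Free-MK1775, 0.0338 in Lipo-MK1775+NLG against Lipo-MK1775 and 0.0841 in the interaction. The highest transcript per gene gave 11 for Free-MK1775+NLG919, 3445 for Lipo-MK1775, 0 for Lipo-MK1775+NLG, 2588 for Lipo-MK1775 against Free-MK1775, 5 for Lipo-MK1775+NLG against Free-MK1775+NLG919, 0 for Free-MK1775+NLG919 against Free-MK1775, 3792 for Lipo-MK1775+NLG against Lipo-MK1775, 3 for Lipo against Free and 3322 for the interaction.

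Scaling to nuclear genes gave 20 for Free-MK1775+NLG919 against the control, 5487 for Lipo-MK1775, 0 for Lipo-MK1775+NLG, 3396 for Lipo-MK1775 against Free-MK1775, 0 for Free-MK1775+NLG919 against Free-MK1775, 4182 for Lipo-MK1775+NLG against Lipo-MK1775, 3 for Lipo against Free and 2 for NLG919. Transcripts with a symbol only gave 7 for Free-MK1775+NLG919, 1 for Lipo-MK1775+NLG, 2 for Lipo-MK1775+NLG against Free-MK1775+NLG919 and 1 for NLG919. Without the 3 libraries, under either scaling, 5 genes were called for Free-MK1775+NLG919 against the control and 0 for it against Free-MK1775; mitochondrially encoded genes went to -0.129, -0.0811 and -0.268 relative to all genes in Free-MK1775+NLG919 against the control, Lipo-MK1775+NLG against Free-MK1775+NLG919 and Free-MK1775+NLG919 against Free-MK1775, and interferon gamma genes to -0.0561 in the last, where the camera direction reversed.

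With the mitochondrial share as covariate 32 genes were called for Free-MK1775+NLG919 against the control, 1 for Lipo-MK1775, 4 for Lipo-MK1775+NLG, 3 for Lipo-MK1775 against Free-MK1775, 3 for Lipo-MK1775+NLG against Free-MK1775+NLG919, 0 for Free-MK1775+NLG919 against Free-MK1775, 3 for Lipo-MK1775+NLG against Lipo-MK1775, 19 for Lipo against Free, 17 for NLG919 and 0 for the interaction. It reversed mt-Nd2 (-2.49), Acsl4 (0.11), Cd274 (0.64), Ido1 (0.15), Ptgs2 (0.011) and Slc7a11 (0.18) in Lipo-MK1775 against the control, mt-Nd2 (-2.27) and Klrk1 (0.67) in Lipo-MK1775 against Free-MK1775, mt-Nd2 (3.10) in Lipo-MK1775+NLG against Lipo-MK1775, and mt-Nd2 (1.12) and Ifih1 (-0.25) in the interaction. The covariate and Lipo-MK1775 nearly coincide, which leaves little to estimate.

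The direction by fry was opposite to camera, which compares with other genes, for MHC class II (1.05 relative to all genes), T cells (0.846), macrophages (0.538) and type I interferon genes (0.547) in Lipo-MK1775 against the control, ribosomal proteins (1.07) and T cells (0.824) in Lipo-MK1775 against Free-MK1775, type I interferon genes in Free-MK1775+NLG919 against Free-MK1775 (0.351), ribosomal proteins (-1.05) and fibroblasts (-0.948) in Lipo-MK1775+NLG against Lipo-MK1775, chemokines in Lipo against Free (0.27) and type I interferon genes in the interaction (-0.889).

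Against genes of the same level, ribosomal proteins went from 0.147 to 0.00982 in Free-MK1775, 0.644 to 0.144 in Free-MK1775+NLG919 and 1.14 to 0.611 in Lipo-MK1775 against the control. They went from 1.07 to 0.633 in Lipo-MK1775 against Free-MK1775, -0.587 to -0.129 in Lipo-MK1775+NLG against Free-MK1775+NLG919, 0.609 to 0.189 in Free-MK1775+NLG919 against Free-MK1775, -1.05 to -0.584 in Lipo-MK1775+NLG against Lipo-MK1775 and -1.63 to -0.813 in the interaction. Further values were -0.473 for mitosis in Lipo-MK1775 against the control, -0.288 against Free-MK1775 and, in the interaction, 0.606 for mitosis and 0.272 for DNA replication. No list in the text changed sign.

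Leaving out 1 library at a time, the count ran from 1 to 28 for Free-MK1775 against the control (28 without negative control replicate 2), 4 to 7855 for Free-MK1775+NLG919 (without its replicate 2 and 1), 3 to 10361 for Lipo-MK1775 (without its replicate 1, and without Free-MK1775+NLG919 replicate 1) and 0 to 26 for Lipo-MK1775+NLG (without Lipo-MK1775 replicate 1, and without negative control replicate 2). It ran from 6 to 10657 for Lipo-MK1775 against Free-MK1775, 1 to 8159 for Lipo-MK1775+NLG against Free-MK1775+NLG919, 0 to 7799 for Free-MK1775+NLG919 against Free-MK1775, 7 to 10776 for Lipo-MK1775+NLG against Lipo-MK1775, 2 to 8910 for Lipo against Free, 1 to 9489 for NLG919 and 2831 to 10636 for the interaction; the low values came without Lipo-MK1775 replicate 1 or Free-MK1775 replicate 2 (for Lipo-MK1775+NLG against Free-MK1775+NLG919, without Free-MK1775 replicate 1 and others) and the high without Free-MK1775+NLG919 replicate 1, or replicate 2 for both averages. Relative to all genes, skin genes ran from 1.25 to -2.66 in Free-MK1775 and 0.982 to -3.07 in Lipo-MK1775+NLG against the control, without negative control replicate 1 and 2. Mitochondrially encoded genes ran from -0.129 to 4.95 in Free-MK1775+NLG919 against the control and -0.268 to 4.62 against Free-MK1775, without Free-MK1775+NLG919 replicate 2 and 1. Mast cell genes ran from 0.552 to 1.67 in Lipo-MK1775+NLG against Free-MK1775+NLG919 and neutrophil genes from 0.187 to 0.463 in NLG919 against none, without Lipo-MK1775 replicate 1 and 2 in the latter. Of list results, 541 stayed the same, 51 lost the call and 8 reversed (450, 160 and 20 under other alternatives). Leaving out a library outside the comparison cannot change the list value.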

Other observations

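The comparison of 7 libraries, that with genes of the same level, the correlations between comparisons and the sum of a pair of pseudogenes were chosen as tests only after the result was seen.

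T cell genes had a median 0.84 above all genes in Lipo-MK1775 against the control (camera adjusted p = 5.84e-06, upward; adjusted p = 0.918 with an estimated correlation), though the members were lower in 11 of 16 and limma called 0 higher and 1 lower. Low genes have less room to fall on this scale, and against genes of the same level the excess was 0.611; over all genes it was 1.08 with a pseudocount of 0.1 and -0.0242 without a filter on low values, still upward by camera. Macrophage and type I interferon genes each lay 0.54 above there, with negative medians (camera adjusted p = 5.8e-05 for each, 0.918 with an estimated correlation). Without Lipo-MK1775 replicate 2 the macrophage value was 0.321, and without negative control replicate 2 the interferon value 0.334, both still called. Against genes of the same level these lists had 0.322 and 0.671, and without a filter on low values both calls ended (-0.333 and -0.324 relative to all genes). Regulatory and exhausted T cell genes (0.316) and MHC class I genes (0.0384) were not called. Cholesterol and fatty acid synthesis genes, which supply membrane lipids, fell in 18 of 20 members with a median of -1.61, or -0.53 relative to all genes (camera adjusted p = 0.0284; adjusted p = 0.918 with an estimated correlation), and the call ended at -0.425 without Lipo-MK1775 replicate 2, -0.472 with the highest transcript per gene, -0.457 when scaled to nuclear genes and -0.599 with transcripts with a symbol only. These libraries had a mitochondrial share of 64.1% and 56%.

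Any MK1775 treatment was compared with the control in the 7 libraries of low mitochondrial share, under median-of-ratios scaling. Prl2c3 (-2.91, SE 0.15, adjusted p = 0.00493) and Il24 (-2.27, SE 0.13, adjusted p = 0.00622) fell by limma, with Rps18-ps6 as the only other gene called and 2623 genes at an unadjusted p under 0.05. Il24, a cytokine, was at 6.59 ± 0.283 FPKM (SD, n = 2) in the control and 0.982 ± 0.103 in Free-MK1775. Mitosis genes had a median of -0.325 (camera adjusted p = 0.000164) and mast cell genes of -1.4 (0.00325 by camera). Macrophage genes had 0.433 (0.00325) and MHC class II and dendritic cell genes 0.762 (0.0135). Tissue markers moved as well, with skeletal muscle at 0.68 (0.0183 by camera) and skin at -1.32 (0.124, not called). For each of these lists the adjusted p was 0.909 with an estimated correlation, and differences in the dissected tissue stay open for them. Without negative control replicate 1 or 2, 0 genes were called by limma (Prl2c3 -2.88 and -2.93, Il24 -2.23 and -2.32), and 1200 without Free-MK1775 replicate 2. The MHC class II call ended at 0.692 without negative control replicate 2 and 0.384 without Free-MK1775+NLG919 replicate 1, where mast cells went to -0.893. Skeletal muscle lost the call at 0.173 without negative control replicate 2, 0.307 without Free-MK1775 replicate 2 and 0.117 without Free-MK1775+NLG919 replicate 1, and was at 1.1 without negative control replicate 1. Skin was at 0.779 and -3.56 without negative control replicate 1 and 2, the latter called, as was -1.6 without Lipo-MK1775+NLG replicate 2.

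Globin genes were higher in the Free than in the Lipo groups, and blood carried over with the tissue stays open. Platelet genes, which blood would bring along, were -0.164 in the Free over the Lipo groups relative to all genes, but 3 of 7 were measured, which makes the test void. A change in the vessels or bleeding with the form stays open. Endothelial genes were lower in the Lipo form in 14 of 14 (-0.239 relative to all genes), a call lost without Free-MK1775+NLG919 replicate 2. At low mitochondrial share their mean was 2.722 and 2.83 in Lipo-MK1775+NLG, and 2.706 to 3.057 in Free libraries. At high share, in both forms, it was 1.294 to 1.976, so the fall cannot be assigned to the form.

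The changes of Free-MK1775+NLG919 and Lipo-MK1775 against their shared control correlated across genes at r = 0.721, where 100 simulated draws with a shared control alone gave 0.498; both comparisons hold libraries of high mitochondrial share. The same correlation was 0.684 between Free-MK1775 and Free-MK1775+NLG919 and 0.339 between Lipo-MK1775 and Lipo-MK1775+NLG. Genes are not independent replicates.

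All 561 bases of Rps18-ps6 lie within Rps18-ps4, and their FPKM summed per library ran from 261.9 to 592.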
